A study of Mus musculus with 2 samples.

How the data were processed

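KDM4A ChIP-seq was done in 3T3-L1 mouse cells that had been transfected and induced to differentiate, with an antibody the labels spell anti-KMD4A (Abcam ab47984) and sequencing on an Illumina GAII, per the labels' protocols. There were 2 libraries, 1 from cells given control siRNA (siCTL) and 1 from cells given siRNAs against GPS2 (siGPS2). Bowtie, HOMER and the mouse genome build mm8 are named in the submitters' processing notes, without roles or settings, and their versions were not given in the sources used here. No step of read filtering is stated.

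For each library the authors deposited aligned reads and a peak list. In the deposited reads, the only measured column is a mapping quality score, a whole number from 0 to 42 that is not normalized, and reads were counted from the lines themselves. In siCTL 3 lines and in siGPS2 6 lines were cut short and were left out. Most alignments spanned 48 bp, 98.6% in siCTL and 98.5% in siGPS2. The deposited peak lists hold other values than signal: only the coordinates of each peak, called per library, with no score and no control named. Every peak was 2000 bp wide. The order of the lists followed strength, with a Spearman correlation across peaks between place in the list and reads within 150 bp of the centre of −0.739 in siCTL and −0.743 in siGPS2. Peak starts were taken to count from 0, as in the BED format, which the peak lists do not state, and all coordinates are printed counting from 1.

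Only 1 read per position and strand was kept in each library. The deposited reads held almost no repeats of a position: 0.137% of siCTL reads and 0.138% of siGPS2 reads. Among reads of high mapping quality (at least 30), 46 siCTL and 16 siGPS2 reads repeated a position, where chance placement would give 7155 and 4357. Repeats had thus been removed before deposit in some way that the sources used here do not state. Among reads of mapping quality below 10 the repeats were 8040 and 6052, against 8375 and 6334 by chance. Read names showed the same run, flow cell and lane in both libraries, and 14 flow-cell tiles held over 100000 reads in both. Whether the deposited reads are all those of the lane is not given in the sources used here, nor is the order in which tiles were read, which was taken from the tile numbers.

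Peaks of the lists that shared at least 1 bp were joined into merged peaks. In each, distinct reads whose 5 prime end lay inside the peak were counted and scaled to the distinct reads of the library (RPM). The ratio siGPS2 over siCTL was given an exact conditional (Clopper-Pearson) 95% interval. A merged peak was called lower or higher when it had at least 30 distinct reads over both libraries, a fold of at least 1.5 and an interval that excluded 1. Background windows, 10 per merged peak, had the same widths and chromosomes and lay away from peaks. Medians carry bootstrap intervals from 2000 draws of the peaks. Overlap was compared with 1000 shuffles of the other list within its chromosomes. Random deals split the pooled reads of each peak or bin between the libraries in proportion to depth, 100 times. Enrichment at peak centres compared reads within 150 bp of the centre with reads 2000 to 10000 bp away. Shares carry Wilson 95% intervals. A peak was taken as mostly of high mapping quality when at least 50% of its reads reached that quality. Regions of high coverage were bins of 100 kb, joined where adjacent, with at least 5 times the genome median in both libraries. Dispersion over bins is the mean squared deviation of the siGPS2 read number from its share of the bin total, divided by the binomial variance, which is 1 on average with counting noise alone.

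Before the data were examined, the comparisons, the 1.5-fold and 30-read criteria and the peaks to be named were fixed: the 10 merged peaks of both lists with the highest mean RPM, and the 10 with the largest fold lower and the 10 with the largest fold higher in siGPS2 among those with at least 30 reads and an interval that excluded 1. Peaks on contigs or the mitochondrial chromosome were not named. The high mapping quality limit, the centre width of 150 bp, the division by tile, the high-coverage regions and the random deals were chosen after.

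The depth, 6559860 and 4940261 distinct reads, set what could be seen. The criteria were tested on simulated data for the 798 merged peaks with at least 30 reads. With the total of each peak kept, 62% of 50 peaks raised 2-fold and 50% of 50 lowered 2-fold were called, as were 96% and 94% at 4-fold. Of 598 unchanged peaks 20 (3.34%) were called, and 96.7% of intervals held the simulated fold. With counts drawn anew, 78% and 32% were called at 2-fold and 100% and 40% at 4-fold, since 19 and 30 of the lowered peaks fell under the minimum of 30 reads. Dispersion planted at 1.26 was recovered at 1.24.

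To ask how far counting noise separates lists, the pooled reads were re-dealt 20 times into libraries of the same depths, and peaks were called with a simple caller written here. It counted reads shifted by 40 bp in windows of 200 bp, at least 4 times the level over the 10 kb around, with at least 7 reads in siCTL and 6 in siGPS2. This caller recovered 46.2% of the deposited siCTL peaks and 54.3% of the siGPS2 peaks. A version that ranked windows and kept as many as each deposited list holds recovered 43.7% and 40.7%. On simulated data with an even background each found 200 of 200 planted peaks. Each planted peak held more reads than the caller needed, so weak peaks were not tested. The deposited peaks had medians of 7 siCTL reads and 6 siGPS2 reads within 150 bp of the centre in their own library.

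Alternatives were all deposited reads, scaling by background reads, 500 bp and 150 bp either side of the centre, a 75 bp shift, minima of 10 and 100 reads, other overlap rules, 100 kb bins, the siCTL library thinned to the siGPS2 depth, high mapping quality only, common tiles or the first tile only, and leaving out contigs or high-coverage bins. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Promoter density, gene lists, gene names at peaks and base composition were left out, since no genome or annotation of mm8 was used here and positions were not converted between builds. No count model across replicates was fitted, as each group held 1 library.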

Results

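The series measured where the histone demethylase KDM4A sat on the genome of 3T3-L1 cells, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). 3T3-L1 is a mouse fibroblast-like preadipocyte line that turns into fat-storing adipocytes when given an adipogenic hormone mixture, and the cells were induced to differentiate, per the labels. KDM4A (also called JMJD2A) removes methyl groups from lysines of histone H3. GPS2 is a subunit of the NCoR/SMRT corepressor complex, in which it acts with the histone deacetylase HDAC3. In ChIP-seq, chromatin fragments bound by an antibody are sequenced, and places where reads pile up (peaks) are taken as sites of the protein. Repeated sequence and extra copies of DNA pile up reads as well, which an input library would show. The 2 groups were cells transfected with a control siRNA (siCTL) and cells transfected with siRNAs against GPS2 (siGPS2), with 1 library per group and no input or control-antibody library. No difference below has a replicate check, no p-value is given, and the amount of GPS2 or of KDM4A in the cells was not among the deposited data.

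The siCTL library held 6568834 aligned reads at 6559860 distinct positions, and the siGPS2 library held 4947088 reads at 4940261 distinct positions. The siGPS2 library thus had 0.753 times the reads of the siCTL library, and 0.817 times in the 14 flow-cell tiles that held over 100000 reads in both. The siGPS2 tiles with over 100000 reads ended earlier in tile order: tile 1207 held 474572 siCTL reads and 1795 siGPS2 reads. Tiles after 1208 held few reads of either library, at most 9330 siCTL reads in tile 1305 and 4666 siGPS2 reads in tile 1304. Reads of high mapping quality made up 83.5% of the siCTL library and 83.2% of the siGPS2 library. The mitochondrial chromosome held 0.0415% of siCTL reads (95% Wilson interval 0.0400 to 0.0431%) and 0.0352% of siGPS2 reads (0.0336 to 0.0369%). Intervals on shares and ratios cover counting error only: reads without molecular identifiers are not independent molecules, and an interval on a ratio compares these 2 libraries, not the 2 conditions. Intervals on medians cover the spread across peaks, resampled as if independent, and likewise compare only these 2 libraries.

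The question set by the series title and design is whether KDM4A binding depends on GPS2. The lists of KDM4A peaks deposited for the libraries held 1657 peaks in siCTL and 1349 in siGPS2, each peak 2000 bp wide. Of the siCTL peaks, 853 (51.5%, 95% Wilson interval 49.1 to 53.9%) were overlapped by a siGPS2 peak, and of the siGPS2 peaks 826 (61.2%, 58.6 to 63.8%) were overlapped by a siCTL peak. With the other list shuffled within its chromosomes, the mean overlap over 1000 shuffles was 0.303% for siCTL and 0.367% for siGPS2. The shuffles placed peaks at random positions, without regard to repeated sequence. Peaks near the top of each list were found in both: all 100 of the first 100 siCTL peaks and 99 of the first 100 siGPS2 peaks were overlapped. The share fell to 25.2% in the later part of the siCTL list (its last 829 peaks) and 38.1% in the last 675 peaks of the siGPS2 list. Those late peaks rested on few reads, with a median of 5 distinct siCTL reads within 150 bp of the centre in the last 100 siCTL peaks and 4 siGPS2 reads in the last 100 siGPS2 peaks. Chromosome 8 held the most peaks of any chromosome, 12.7% of the siCTL list and 12.8% of the siGPS2 list, against 6.77% and 6.79% of the reads.

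Joining the lists gave 1910 merged peaks, of which 635 held peaks of both lists, 770 peaks of the siCTL list only and 505 peaks of the siGPS2 list only. Of those 635, 119 were mostly of high mapping quality, against 418 of the 770 and 258 of the 505. Merged peaks shared by the lists thus lay mostly where reads were not of high mapping quality. Merged peaks of both lists had nearly the same read density in the libraries, with a median log2 ratio (siGPS2 over siCTL, in reads scaled to the distinct reads of each library, RPM) of 0.07 (95% bootstrap interval over peaks 0.03 to 0.10). Peaks of the siCTL list only had a median of −0.21 (−0.27 to −0.16) and peaks of the siGPS2 list only a median of 0.28 (0.22 to 0.41). Each of those classes was picked for reads in its own library, so its median leans towards that library by construction. Over all merged peaks the median was 0.03 (−0.01 to 0.06), and over 18801 background windows of the same widths it was −0.01. Merged peaks took in 0.796% of siCTL distinct reads (95% Wilson interval 0.789 to 0.803%) and 0.852% of siGPS2 reads (0.844 to 0.861%), over 4157869 bp. The summed ratio was 1.09 (1.08 to 1.11) over the 1115 merged peaks with fewer reads of high mapping quality and 0.997 (0.970 to 1.02) over the 795 mostly of high mapping quality.

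**Figure D1:**
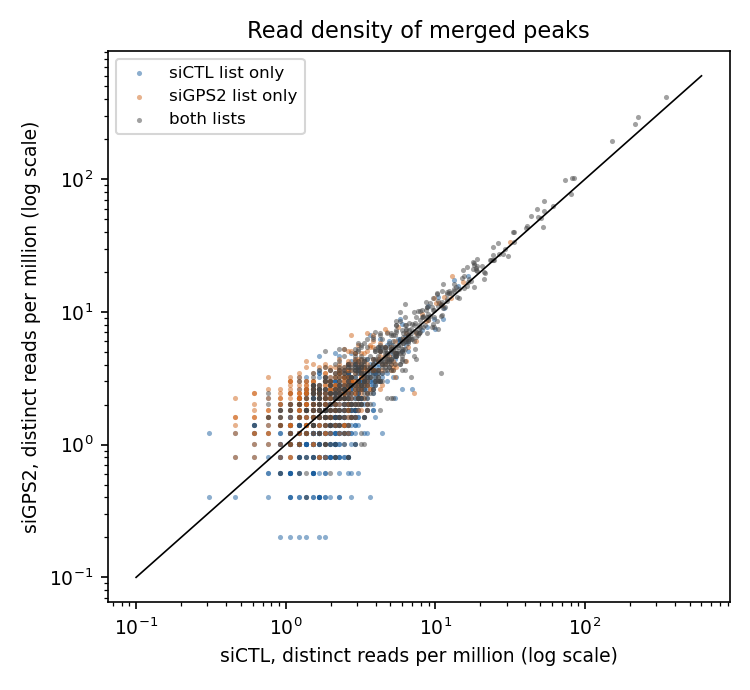
Read density (RPM, distinct reads scaled to library depth) of each merged peak, siCTL on the x axis and siGPS2 on the y axis, both on log scales, with 1 point per merged peak coloured by the list that held it and a line where the libraries are equal. Of the merged peaks, 1909 are drawn and 1 with no reads in a library is not; points lie along the line, and the peaks of a single list spread to the side of the library that called them.

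Peak centres stood above their surroundings in both libraries, whichever list they came from. Many peaks were overlapped by the other list, 853 of the siCTL list and 826 of the siGPS2 list. The second library was thus not independent of the list, and enrichment was not worked out apart for peaks of a single list. Among peaks whose reads were mostly of high mapping quality, the 567 of the siCTL list had 5.44 times (5.25 to 5.62) the siCTL read density of the flanks within 150 bp of the centre, and 3.72 times (3.56 to 3.90) the siGPS2 density. The 391 such peaks of the siGPS2 list had 5.84 times (5.58 to 6.11) the siGPS2 flank density and 4.33 times (4.14 to 4.53) the siCTL density. Each library was the higher of the pair on its own list, which had been called on its reads. Over the other 1090 peaks of the siCTL list siGPS2 was the higher, at 10.2 times (10.04 to 10.4) against 9.84 times (9.68 to 9.99) in siCTL, and over the other 958 of the siGPS2 list the values were 10.8 times (10.7 to 11.0) in siGPS2 and 9.35 times (9.20 to 9.50) in siCTL.

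**Figure D2:**
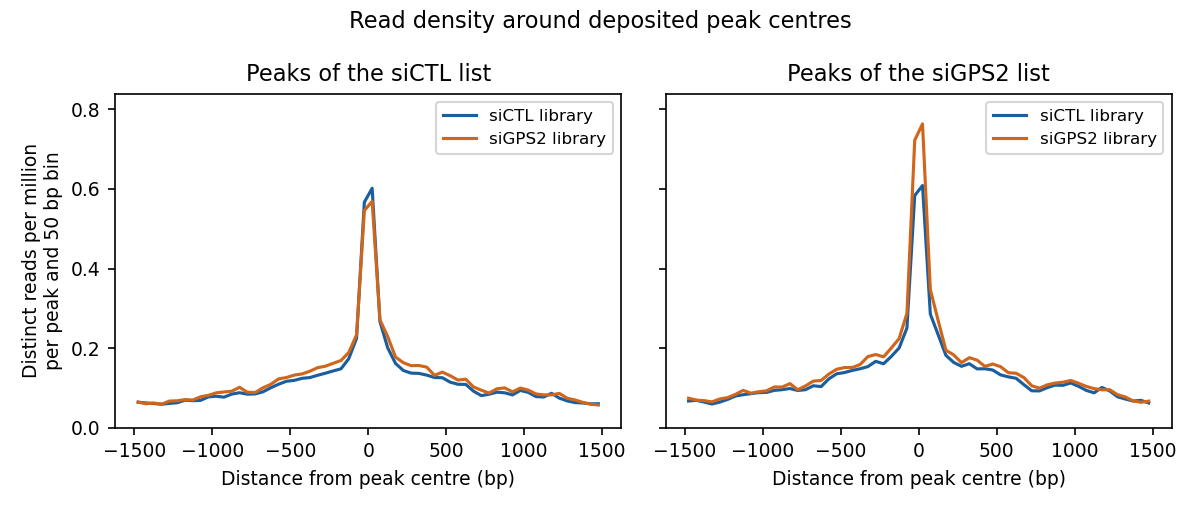
Mean read density (RPM) per peak in 50 bp bins (y axis) against the distance from the peak centre in bp (x axis), for all peaks of the siCTL list (left) and of the siGPS2 list (right), with 1 line per library. Both libraries rise sharply at the centres of both lists, at 8.67 times the flank density in siCTL and 8.50 times in siGPS2 over the siCTL list, and at 8.34 and 9.82 times over the siGPS2 list.

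Of the 798 merged peaks with at least 30 distinct reads over both libraries, 12 were lower in siGPS2 and 22 were higher, by at least 1.5-fold and with a counting interval that excluded a ratio of 1. The other 764 were called neither lower nor higher. Dealing the pooled reads of each peak to the libraries at random, 100 times, gave a mean of 12.4 lower and 13.1 higher, with up to 22 of each. The total of 34 was reached or passed in 6 of the 100 deals. The number of lower peaks was therefore near the mean of the deals, while the number of higher peaks equalled their maximum. Without the fold criterion, 41 peaks had an interval above 1 and 12 an interval below 1, which were not compared with the deals. When the siCTL library was thinned to the siGPS2 depth, 13 were lower and 14 higher, and with a minimum of 100 reads none passed in either direction. The peaks below are those with the largest folds, and the nearest genes were not assigned because no annotation of mm8, the build of the files, was used here.

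Among the lower peaks named, the most reads were on chromosome 17 at 4581809 to 4583810, a peak of both lists: 71 distinct siCTL reads against 17 in siGPS2, a ratio of 0.318 (95% exact conditional interval 0.176 to 0.545). Within 150 bp of its centre there were 49 siCTL reads and 6 siGPS2 reads. In reads of high mapping quality alone it had 7 against 5, a ratio of 0.952 (0.238 to 3.49), so the call was lost there. The lowest ratio was on chromosome 6 at 132428455 to 132430454, a peak of the siCTL list only, with 29 reads against 6 (0.275, 0.0933 to 0.673). A peak on chromosome 4 at 146361138 to 146363137 was in the siGPS2 list only yet had 47 siCTL reads against 12 in siGPS2 (0.339, 0.164 to 0.649). The other 7 peaks named as lower had ratios of 0.375 to 0.443: they began at 15158238 on chromosome 5, 125841553 on chromosome 6, 12821708 and 66274266 on chromosome 13, 3278456 on chromosome 8, 55832752 on chromosome 17 and 174604838 on chromosome 2. Reads of high mapping quality were 13.6% of those in the chromosome 17 peak at 4581809 and 17.1% of those in the peak with the lowest ratio, against 97.3% in the chromosome 8 peak.

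The highest ratio was on chromosome 16 at 18789928 to 18791927, a peak of the siGPS2 list only, with 9 distinct siCTL reads against 21 in siGPS2, a ratio of 3.10 (1.36 to 7.68). Next came chromosome 8 at 126467165 to 126469164 with 11 reads against 23 (2.78, 1.30 to 6.31), a peak of the siCTL list only, and chromosome 7 at 39102059 to 39104071 with 12 against 25 (2.77, 1.34 to 6.04), a peak of both lists. Among the higher peaks named, the largest total was on chromosome 17 at 6213394 to 6215393, a peak of the siGPS2 list only, with 18 reads against 33 (2.43, 1.33 to 4.59). The others began at 23532452 on chromosome 11, 176824275 and 58961351 on chromosome 2, 60809647 on chromosome 19, 109919460 on chromosome 8 and 75736363 on chromosome 15, with ratios from 2.66 down to 2.16. All reads of the chromosome 16, 11 and 15 peaks were of high mapping quality, while none of the reads of the chromosome 8 peak at 126467165 were. Merged peaks of the siGPS2 list only held 10 of the 22 higher peaks, above the 8 that any of the 100 deals gave for that class. That list had been called on siGPS2 reads, which the deals do not allow for. An excess of higher peaks in it could come from that choice alone.

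**Figure D3:**
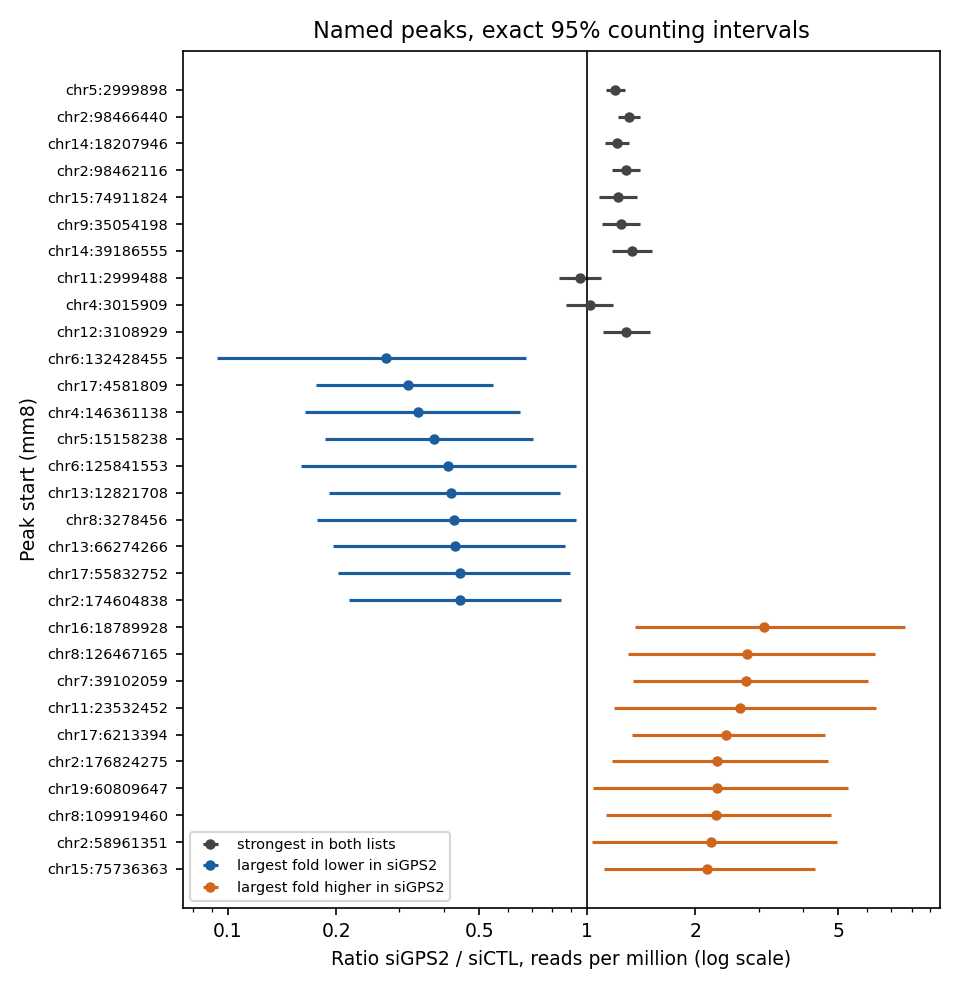
Ratio of siGPS2 to siCTL read density in RPM (x axis, log scale) for the 30 named merged peaks, listed by chromosome and start (y axis), with bars for exact 95% counting intervals and a line at a ratio of 1. The strongest peaks lie close to 1 with narrow bars, while the largest folds, from 0.275 to 3.10, carry wide bars.

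The 10 strongest peaks of both lists had a higher read density in the siGPS2 library: summed, 9008 distinct siCTL reads against 8265 in siGPS2, a ratio of 1.22 (1.18 to 1.26). With the siCTL library thinned to the siGPS2 depth the ratio was 1.12 (1.08 to 1.16), and the intervals of the chromosome 9, chromosome 12 and second chromosome 14 peaks named next reached 1. The strongest lay at the start of the assembled sequence of chromosome 5, at 2999898 to 3003537, with 2270 siCTL reads against 2047 (1.20, 1.13 to 1.27). A pair of neighbouring peaks on chromosome 2, at 98466440 to 98468978 and 98462116 to 98464705, had ratios of 1.31 (1.21 to 1.41) and 1.28 (1.17 to 1.40). Peaks on chromosome 14 at 18207946 to 18211006 and 39186555 to 39188555 had 1.21 (1.12 to 1.31) and 1.33 (1.17 to 1.51). Chromosome 15 at 74911824 to 74914991, chromosome 9 at 35054198 to 35056200 and chromosome 12 at 3108929 to 3110930 had 1.22, 1.24 and 1.29, with intervals above 1. The remaining 2, at 2999488 to 3004993 on chromosome 11 and 3015909 to 3018754 on chromosome 4, had ratios of 0.953 (0.833 to 1.09) and 1.01 (0.872 to 1.18).

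Reads in these strongest peaks were mostly not of high mapping quality: the median share of high mapping quality over the 10 was 5.07% and the highest 30.3%. Their share of the reads also fell along the flow cell, from 1.07% of siCTL reads and 1.15% of siGPS2 reads in the first of the 14 tiles held by both libraries to 0.0799% and 0.104% in the last. The ratio of all deposited reads was 1.07 (1.03 to 1.12) in the first tile and 1.30 (1.11 to 1.52) in the last.

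**Figure D4:**
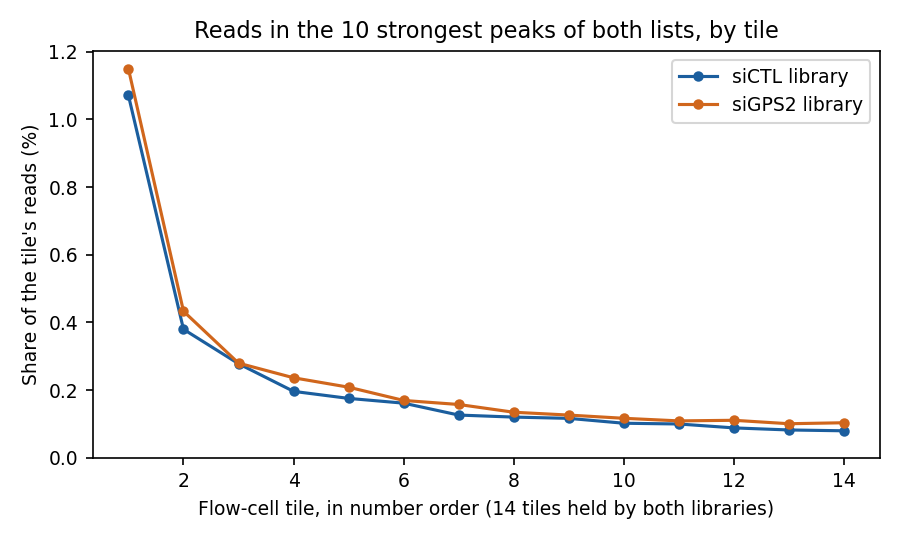
Share of each tile's deposited reads, in percent (y axis), that fell in the 10 strongest peaks of both lists, against the order of the 14 flow-cell tiles held by both libraries (x axis), with 1 line per library. The share falls from 1.07% to 0.0799% in siCTL and from 1.15% to 0.104% in siGPS2.

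Chromosome totals, peaks included, differed little: over 20 chromosomes (the autosomes and X) the ratio ran from 0.982 on chromosome X to 1.03 on chromosome 11, with 7 intervals above 1 and 8 below. Of 220300 bins of 10 kb with at least 30 reads, 4114 were lower in siGPS2 and 4387 higher by the same criteria, against means of 3856 and 4130 and maxima of 4025 and 4305 over 100 random deals. With bins of 100 kb, 13 of 25738 were lower and 4 higher, against means of 7.90 and 5.79 and a maximum of 16 for each over 100 deals. The mitochondrial chromosome was lower in siGPS2, with a ratio of 0.847 (0.797 to 0.900).

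The densest stretch made up mostly of reads of high mapping quality was on chromosome 10 at 116600001 to 117200000, at 50.4 times the genome median in siCTL and 53.8 times in siGPS2, with 94.2% of reads of high mapping quality. Its siCTL and siGPS2 reads, 73179 and 58073, gave a ratio of 1.05 (1.04 to 1.07). The stretch formed a broad block with sharp edges in both libraries and held 2 merged peaks. Whether the block is there without the antibody was not analysed here, for want of an input library. Its ratio was 1.003 (0.961 to 1.05) in the first of the 14 common tiles and 1.0996 (1.05 to 1.15) in the last.

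**Figure D5:**
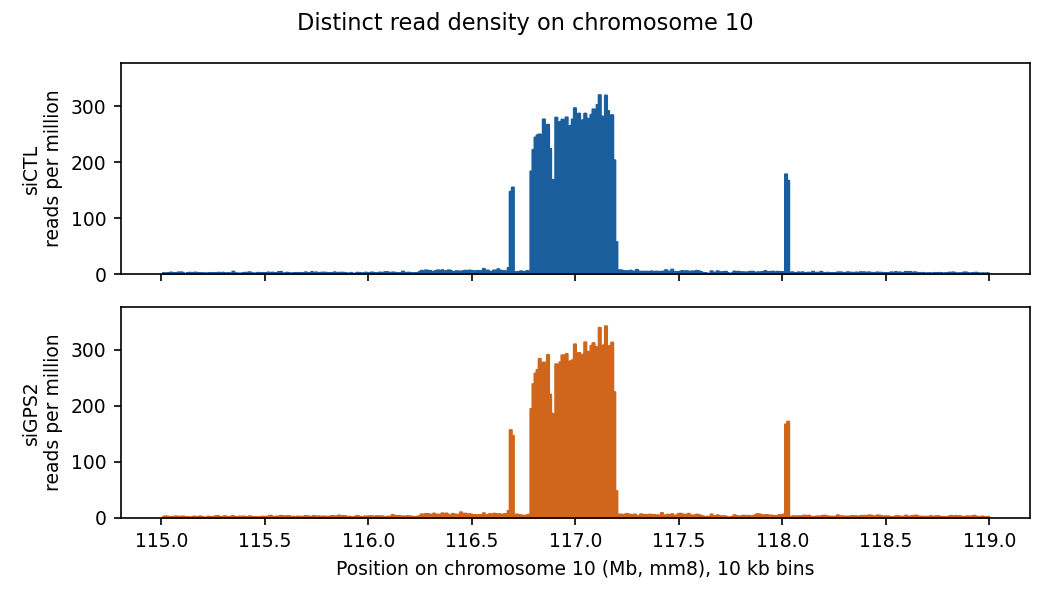
Read density (RPM) in 10 kb bins (y axis) along chromosome 10 in Mb of mm8 (x axis), siCTL above and siGPS2 below. A broad block with sharp edges stands within 116600001 to 117200000, at 50.4 and 53.8 times the genome median over that stretch, and a narrow block lies between 118000001 and 118100000 in both libraries.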

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

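The division of the re-dealing test by library, its judgement from both callers, the split of the strongest peaks by their own intervals and the raw read number test were chosen after results were seen, as was the dispersion test on reads of high mapping quality. Some stretches of nuclear chromosomes held no deposited peak, were outside every comparison of peaks, and stood far above the genome median in both libraries. Chromosome 9 at 3000001 to 3100000 lay 113 times above the median of 100 kb bins in siCTL and 134 times in siGPS2, with 1.01% of its reads of high mapping quality. Chromosome 10 at 106600001 to 106700000 lay 27.6 times above it in siCTL and 26.8 times in siGPS2, with 98.5% of reads of high mapping quality. Chromosome 10 at 118000001 to 118100000 lay 10.2 times above it in siCTL and 10.2 times in siGPS2. Chromosome 17 at 39400001 to 39500000 lay 12.4 times above it in siCTL and 15.4 times in siGPS2, a ratio of 1.22 (1.16 to 1.28).

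The first pattern weighed was that many peaks stood in a single list. With the fixed threshold, 41.9% of siCTL calls were overlapped, above the 20 random re-deals (36.2 to 41.3%), and 30.2% of siGPS2 calls, below them (32.1 to 36.1%), but siGPS2 had more calls than any re-deal, 1362 against at most 1220, which moves both shares. With the number of calls fixed, 21.1% of siCTL calls (re-dealt 19.98 to 21.1%) and 25.6% of siGPS2 calls (24.7 to 25.8%) were overlapped, though that caller recovered only 43.7% and 40.7% of the deposited peaks. Of all merged peaks 34 passed the fold and interval criteria, within the 39 that random deals reached, as did 9 of the siCTL list only, within 12. Of the siGPS2 list only 11 passed, a total reached in 4 of 100 deals, with 10 higher against at most 8. The deals do not allow for a list picked on its own library's reads, so the 10 cannot be told from that choice. The re-deals collapsed positions that the libraries shared, which the real libraries kept. The siCTL overlap was at or above all 20 with both callers, so the re-deals may understate chance overlap and decide neither list. Counting noise and list selection stay open for both lists. An effect of GPS2 siRNA, or of any other difference between these 2 preparations, stays open and was not tested.

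The next was that the strongest peaks were higher in siGPS2. Summed over the 10, reads of high mapping quality gave 1.22 (1.09 to 1.37). That argues against chance placement of multi-placed reads as the whole cause of the summed ratio. In those reads the chromosome 2 pair had 1.44 (1.17 to 1.77) and the other 8 had 1.13 (0.979 to 1.30). The split was made on these same reads, by each peak's own interval, so it cannot say at which of the peaks chance placement acts. Removal of repeated sequences before deposit could saturate these peaks sooner in the deeper library: their share of siCTL reads fell 13.4-fold from the first to the last common tile. The highest raw ratio of read numbers, 1.002, restates the same reads, and thinning siCTL to equal depth (1.12, 1.08 to 1.16) acts only on the positions collapsed here, so neither bears on removal before deposit. The ratio was 1.07 in the first tile (1.03 to 1.12) and 1.30 in the last (1.11 to 1.52). The rule written before this test was run asked for intervals that do not meet, and these meet narrowly. The division by tile had itself been chosen after the data were examined. Intervals that meet do not show equal ratios, so the rule cannot decide. Saturation and an effect of the siRNA were thus not told apart for these 10 peaks. In the first of 20 slices of the first tile, looked at only after, the ratio was 1.02 (0.926 to 1.12), while stretches holding these peaks went from 0.999 to 1.48 (1.02 to 2.14) between the first and last tile on chromosome 14, from 0.989 to 1.04 (0.766 to 1.41) on chromosome 5 and from 1.097 to 1.02 (0.762 to 1.35) on chromosome 2.

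The last was that 100 kb bins varied between the libraries beyond counting noise, with a dispersion of 1.19 against at most 1.02 in 100 random deals. It was 1.17 in reads of high mapping quality, 1.16 without bins of extreme coverage and 1.17 in the tiles held by both libraries, each above every deal, which argues against multi-placed reads, a few extreme bins and tiles held by a single library as the whole cause. Alternate tiles within a library, without bins of extreme coverage, differed no more than chance, at 1.01 in siCTL and 0.999 in siGPS2. Those sets held fewer reads per bin than the libraries compared above. Excess dispersion grows with reads per bin, so these 2 values are not on the same scale as the others. A trend with base composition was not analysed here, and a difference in library preparation or an effect of GPS2 siRNA remains untested with 1 library per group.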

How the results depend on the processing

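High mapping quality, 150 bp either side of the centre, the tile and high-coverage settings, the first part of each list, overlap without contigs, and thinned bins were added after seeing the data. Of the summary values under other settings, 70 kept their direction and side of a ratio of 1, or stayed within the interval or 1.5 times the count, 38 moved and 1 reversed. In distinct reads, the strongest peaks kept a summed ratio above 1 under each setting, at its lowest 1.12 (1.05 to 1.18) in the first tile, where all deposited reads gave 1.07 (1.03 to 1.12). None of these settings restores reads removed before deposit, so a ratio kept above 1 does not argue against saturation. In the first of 20 slices of that tile, all deposited reads gave 1.02 (0.926 to 1.12). Of the ratios of named peaks, 241 kept their direction and whether the interval excluded 1. Another 45 kept the direction with an interval that reached 1, and 5 reversed. The fold and 30-read criteria of a call were not applied to these ratios. Ratios with fewer than 10 reads over both libraries under a setting were left out of these totals, as were peaks that a setting dropped. With 500 bp either side of the centre, the median log2 ratio of siCTL-only peaks was −0.33, with 6 peaks lower and 8 higher. A minimum of 10 reads gave 39 lower and 38 higher, and a minimum of 100 gave 0 and 0, as more or fewer peaks were tested. Thinned to equal depth, 13 were lower and 14 higher. With high mapping quality, medians were 0.12 in both lists, −0.12 in siCTL only and 0.42 in siGPS2 only, with 3 lower and 7 higher, and 0.287% and 0.298% of siCTL and siGPS2 reads in peaks. Within 150 bp, medians were −0.91 in siCTL only and 0.99 in siGPS2 only, with 1 lower and 2 higher, and 0.270% and 0.287% of reads. In the first tile the medians were 0.23 in both lists, 0.25 in siCTL only, a reversal, and 0.25 in all, with 0 lower and 0 higher, at so few reads per peak that the medians follow the ratio of tile depths. There the strong chromosome 15 peak at 74911824 reversed to 0.860 (0.570 to 1.29). Peaks whose interval had already held 1 crossed it, to 1.19 on chromosome 11 at 2999488 and 0.721 on chromosome 4 at 3015909. The chromosome 4 peak also gave 0.987 thinned and 0.994 in common tiles. The first part of each list held 828 and 674 peaks, overlapped at 66.2% and 78.5%. A 50% reciprocal overlap gave 49.1% and 58.3%. Centres within 1000 bp had to give the same, since for peaks of this equal width it is the same rule, though the totals above count it separately. Reads in peaks were 0.865% and 0.929% with all deposited reads, and 0.789% in siCTL without contigs. Bins of 100 kb gave 13 lower and 4 higher. Otherwise the cause was not tested. Promoter settings were not run, for lack of an mm8 annotation, nor were score limits, as the lists hold no score. No paired analysis was possible because each group held 1 library. Depth limited most peaks: the median was 15 siCTL and 12 siGPS2 reads, and only 798 of 1910 reached the minimum of 30 reads that a call needed.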

Other observations

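The divisions by tile and by mapping quality given here were chosen after the data were seen. Stretches of high coverage differed in how their share of the reads moved along the flow cell. On chromosome 9 at 3000001 to 3100000, 1.89% of siCTL reads and 1.86% of siGPS2 reads of the first tile fell in that stretch (ratio 0.988, 0.955 to 1.02), against 0.202% and 0.248% in the last common tile (1.23, 1.11 to 1.35). Chromosome 2 at 98400001 to 98500000, which holds a pair of the strongest peaks, took 0.516% and 0.566% of first-tile reads and 0.0285% and 0.0290% of last-tile reads, with ratios of 1.097 (1.03 to 1.17) and 1.02 (0.762 to 1.35). Chromosome 11 at 3000001 to 3100000 lay 31.0 times above the genome median in siCTL and 33.5 times in siGPS2, and its share went from 0.109% to 0.106% of siCTL reads and from 0.128% to 0.108% of siGPS2 reads between those tiles, with ratios of 1.17 (1.02 to 1.35) and 1.01 (0.873 to 1.17).

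Regions of high coverage numbered 19, took in 2.44% of siCTL reads and 2.60% of siGPS2 reads and held 56 merged peaks. In 9 of them most reads were of high mapping quality. Chromosome 1 at 189300001 to 190000000 was a broad stretch of this kind, at 5.59 times the median in siCTL and 5.65 times in siGPS2 with a ratio of 0.9996 (0.969 to 1.03). Chromosome 2 at 77600001 to 77800000 had 5812 siCTL reads and 4394 siGPS2 reads, with a ratio of 1.004 (0.965 to 1.04).

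The mitochondrial chromosome held a lower share of siGPS2 reads in the first tile too, with a ratio of 0.770 (0.601 to 0.983). In the last common tile its ratio was 0.844 (0.656 to 1.08), with an interval that reached 1. Among distances of 60 bp or more, reads on opposite strands stood apart most often by 80 bp in siCTL, at 1.22 times the level at long distance. In siGPS2 the highest was at 60 bp, the shortest searched, at 1.18 times. There 90 bp also gave 1.18 times, so no single distance stood out in siGPS2. Across 2523 bins of 1 Mb, which are not independent replicates, the log2 ratio of siGPS2 to siCTL in one set of alternate tiles had a Pearson r of 0.363 with that in the other set.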
